A study of Mus musculus with 28 samples.

How the data were processed

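The series holds 28 libraries of polyadenylated RNA from mouse testes, read on the Ion Proton with an Ion Total RNA-seq kit, per the labels' protocols. Of these, 10 come from sorted Sertoli cells that carry a red reporter under Amh-Cre, in 5 stage groups of 2, and 18 come from whole testes of NANOS2 KO mice on the CD1 background, 2 for each of 9 days. The labels name Sertoli as the cell type of the knockout libraries, while their source is whole testis; they were treated as whole testis. The extraction protocol in the labels speaks of sorted germ cells, and the strain label of group A replicate 1 differs from those of the other sorted libraries; all libraries were kept.

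Per the submitters' processing notes, reads were handled with Bowtie, TopHat and Cufflinks against mm10; versions, the counting step, the annotation and any pooling are not given in the sources used here. The deposited count tables hold raw counts (whole numbers) for 43280 gene rows, 1 column per library. The 2 deposited tables named FPKM hold CPM: each value equals the CPM computed from the count and its library total, to within 0.0005, with no gene length in it. Every column was used. In the count table of the knockout, 2 columns share 1 header of day 42; they are called library 1 and library 2, and their replicate number was taken from the CPM column with the same values. Spreadsheet conversion had turned 27 gene symbols into dates; these took 0.215 to 0.332% of the counts and are not named. Of all symbols, 91.1% are in the GENCODE M21 annotation of GRCm38, which gave gene positions.

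Total counts ran from 1901700 to 5279700 in sorted libraries and from 1336700 to 4370100 in the knockout, each to 5 digits, so that 3 counts equal 0.568 to 1.58 CPM and 0.686 to 2.24 CPM. Upper limits and floors taken from 3 counts cover counting error only. Between 18701 and 22160 genes had a read in a sorted library, and between 16779 and 19621 in a knockout library.

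Counts were filtered with filterByExpr, scaled with TMM and tested with edgeR 4.0.16 quasi-likelihood F tests in R 4.3.3. Tests covered 14331 genes in sorted libraries, 13065 in the knockout and 15777 in the joint fit. The biological coefficient of variation was 0.268, 0.122 and 0.192. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 5 stage groups were compared by an F test, each against the mean of the others, and in steps along the cycle. The knockout days were compared by an F test, a straight line and a cyclic fit with a period of 8.6 days. The joint fit compared the knockout with all sorted groups, with group D, and with groups A, B, C and E. Both tables hold raw counts, so they were fitted together; TMM factors ran from 0.796 to 0.887 in sorted libraries and from 1.07 to 1.14 in the knockout. CPM means in the text of the first 2 sets use the scaling within each set, and those of the third the joint scaling, so a gene's level can differ between the parts. A log2 CPM used a prior count of 2. Folds against a group with 0 counts were computed with a floor of 3 counts over the group.

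The groups, the comparisons, the tests, the gene lists and the rule for naming genes were chosen before the data were examined, as were the alternatives, except those named as added. The rule takes Nanos2 first. It then takes the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 4 for group D and for the knockout against sorted cells, 4 and 4 for the other stage groups, and the 6 smallest p for the F tests, the cycle and the line. Unnamed clones and predicted, ribosomal and small RNA genes are left out. From each list it takes up to 2 called members with the smallest p in each direction, or else the 2 most expressed. The largest folds picked this way are prone to overstatement. Some genes that the rule takes are not reported.

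The lists are Sertoli core, androgen-responsive, retinoid, junction, protease, lysosome, niche growth factor, glycolysis, cholesterol, immediate early, clock and cell cycle genes, spermatogonia, spermatocytes, round and elongating spermatids, Leydig, myoid, macrophage, endothelial, stroma and blood genes. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with p-values adjusted over the lists of a contrast, and again with an estimated correlation. Some genes stand in more than 1 list, among them Espn and Rhox5, and Sertoli cells express members of the lists of other cells. Reads of near-identical gene copies, such as the Klk1b, H2, Hsd3b and Prss families, are of uncertain assignment, since the counting step is not given.

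Alternatives were RLE scaling, no filter, DESeq2 1.42.0, the replicate number as a block, limma with trend on log2(CPM + 1), with 0.1 in place of 1 and with no filter, the germ cell lists as a covariate, scaling by the Sertoli core list, leaving out the lists of other cells, and leaving out each library in turn. The alternatives on normalised values had been planned for FPKM and were run on the deposited CPM, which carry no TMM factors. Leaving out a library kept the genes tested with all libraries, and a group then left with 1 library was assumed to vary like the others.

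The tests were also run on simulated data with known changes. For group D, 32.8% of genes with a log2 change of 1 were recovered, 88.9% at 2 and 94.2% at 3, and 5.92% of the calls were false. For the knockout against sorted cells 93.5% were recovered at 1. The cyclic fit recovered 82.4% at 1. Each simulation used 1 coefficient of variation for all genes, no correlation between genes and few changed genes, 199 for group D. Real genes differ in their spread, so these shares do not carry over to the real calls.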

Results

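Gene expression was measured by sequencing of polyadenylated RNA in 28 mouse libraries from animals whose spermatogenesis had been synchronised. The animals received WIN 18,446, a compound that blocks retinoic acid synthesis, for 7 days, then retinoic acid, and tissue was taken 42 to 50 days later. Sertoli cells, the somatic cells that support germ cells in the seminiferous tubule, were sorted from testes with germ cells through a red fluorescent reporter switched on by Amh-Cre. These 10 libraries form 5 groups of 2 by the stages of the seminiferous cycle that dominated: A (XI-XII), B (I-III), C (IV-VI), D (VII-VIII) and E (IX-X). The other 18 libraries are whole testes of NANOS2 KO mice, which lack germ cells, 2 for each of 9 days from 42 to 50. Total counts ranged from 1901700 to 5279700 per sorted library and from 1336700 to 4370100 per NANOS2 KO library. Mitochondrially encoded genes took 4.61 to 12.5% of the counts in sorted libraries and 0.715 to 3.24% in the knockout. Group D held the highest and the lowest of the sorted shares. Nothing in the labels says that replicates are separate animals, so each p-value measures the spread between these samples.

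Nanos2, the targeted gene, had 2 counts over the sorted libraries, 1 in group A replicate 1 and 1 in group D replicate 2, and 0 counts in each NANOS2 KO library. A count of 0 allows up to 0.686 to 2.24 CPM in those libraries, counting error only. The level in sorted cells was as low, so the gene does not check the genotype labels. Transcripts of germ cells do separate the sets. The 17 genes of the elongating spermatid list took 1.28% ± 0.53 of the counts (SD, n = 10) in sorted libraries and 0.00013% ± 0.00012 (SD, n = 18) in the knockout.

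The first comparison asks how far the transcriptome of sorted Sertoli cells moves along the cycle. Sorted libraries also hold transcripts of the germ cell lists, so a difference between stage groups need not lie in Sertoli cells. Groups C and D shared high levels of genes that were low in group A. S100a1, a calcium-binding protein, stood at 175 CPM ± 66.7 in C and 155 CPM ± 23.3 in D, against 3.26 CPM ± 1.17 in A (SD, n = 2 each). Ndrg4 was at 352 CPM ± 88.7 in C, 366 CPM ± 42.0 in D, 29.4 CPM ± 0.29 in E and 15.7 CPM ± 2.98 in A. Myl6b, a myosin light chain, reached 505 CPM ± 120 in C and 21.9 CPM ± 11.2 in A. Pcyt1b, an enzyme of phosphatidylcholine synthesis, and Gsta2, a glutathione transferase, had their highest means in D (73.1 CPM ± 9.23) and C (126 CPM ± 23.9). Tnp1, a transition protein of elongating spermatids, ran the other way, with 2509 CPM ± 144 in A and 208 CPM ± 39.6 in D. These 6 genes had the smallest p in the F test, with adjusted p from 6.01e-05 to 0.000311 (edgeR quasi-likelihood). In all, 1156 of 14331 genes differed among the 5 groups. The count was 386 without group D replicate 1, 471 without group D replicate 2, 594 without group E replicate 2 and 634 without group E replicate 1.

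**Figure D1:**
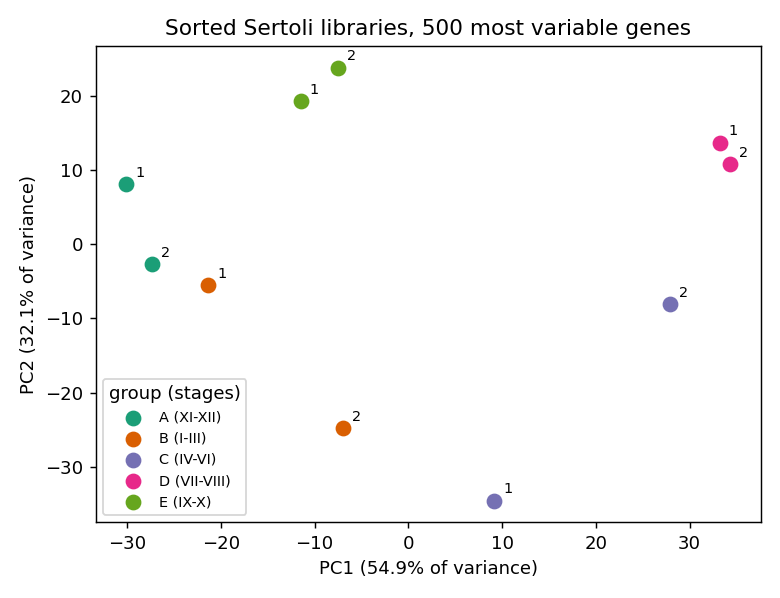
Principal components of the 10 sorted libraries over the 500 most variable genes (log2 CPM), each point 1 library, coloured by stage group and numbered by replicate. The first component (54.9% of the variance) puts A at the left and D at the right, and the second (32.1%) parts E from B and C.

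Groups A and B lay closest, with a mean distance of 1.40 ± 0.44 (root mean square log2 CPM difference over the 500 most variable genes, SD over pairs of libraries), followed by A and E at 1.44 ± 0.17. Groups A and D lay farthest apart at 2.91 ± 0.04. Relative to the mean of all pairs, group D was 1.12 ± 0.25 from the rest, C 1.04, A 0.99, E 0.93 and B 0.92. These values have no test, and the SD of group D's pairs covers the gaps between groups. The 2 libraries of group C stood 1.72 apart, more than those of any other group, and C to D came to 1.86 ± 0.70. The 2 libraries of group B stood 1.40 apart, so the distance from A to B is no larger than that between replicates of B.

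The comparison of group D, stages VII-VIII, with the mean of the other groups called the most genes. Genes high in D included Actn3, an actin cross-linker, at 624 CPM ± 104 in D against 14.1 CPM ± 2.12 in A (log2 fold change 3.38, SE 0.33, adjusted p = 0.000246). Stra6, a receptor for retinol uptake, was at 221 CPM ± 17.9 in D and 5.08 CPM ± 0.34 in B (log2 3.32, SE 0.52). Ano1, a chloride channel, rose by 3.15 (SE 0.33) on the log2 scale. The largest rise was that of Syt13, 4.31 (SE 0.62), with 0.43 CPM ± 0.15 in B. Fam107a, Tmprss6, Clstn3, Rapgef5 and Prss35 were also among the 10 largest, with log2 changes from 3.29 down to 2.97. Genes low in D included Gas6, a ligand of receptors for the uptake of dying cells, at 145 CPM ± 17.7 in D and 1042 CPM ± 132 in B (log2 -2.46, SE 0.26). The phosphatase gene Ptpn7 had the largest fall, -4.14 (SE 0.55), from 121 CPM ± 49.6 in C to 2.56 CPM ± 0.01 in D. Mest (-3.90), the heme synthesis gene Alas2 (-3.68), Defb33 (-3.63), Chdh (-3.42), the protamine Prm1 (-3.42), the dynein chain Dnaic2 (-3.32), the histone variant H2afb1 (-3.18) and Paqr5 (-3.10) followed. In the GRCm38 annotation Actn3 lies on chromosome 19 from 4861216 to 4877909, Stra6 on chromosome 9 from 58063788 to 58153996, Prm1 on chromosome 16 from 10796326 to 10805839 and Rhox5 on chromosome X from 37804842 to 37808876, each annotated as a protein-coding gene.

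**Figure D2:**
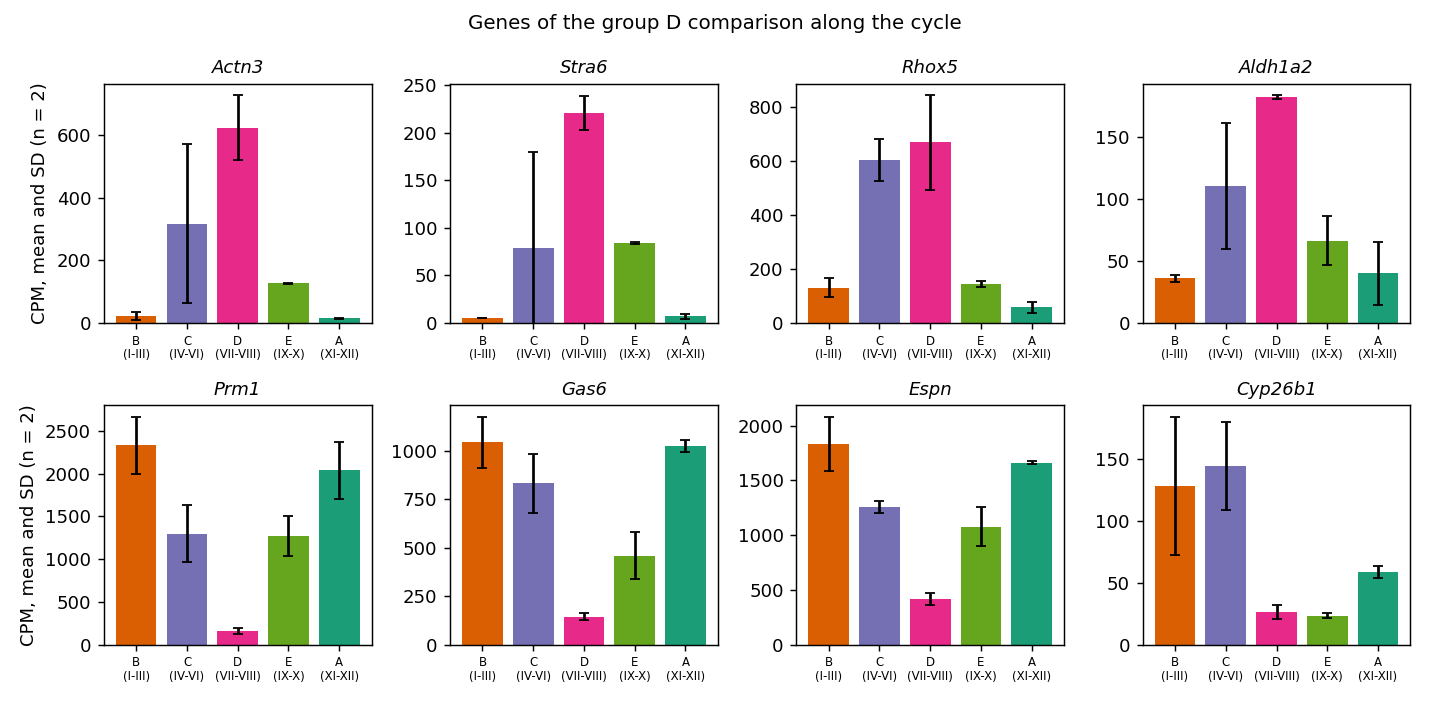
CPM of 8 genes in the sorted libraries by stage group, in the order of the cycle (bars, mean; error bars, SD; n = 2 per group). Actn3, Stra6 and Aldh1a2 have their highest mean in D, with 624, 221 and 182 CPM, while Prm1 and Gas6 have their lowest there, with 156 and 145 CPM.

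In all, 625 genes were higher and 614 lower in D, of 14331 tested (8.65%), and 1083 of these differed by at least 2-fold. The calls rest on the 2 libraries of group D: 289 were left without replicate 1, 402 without replicate 2, and 768 without group E replicate 1. Named genes past the threshold in the full fit and not with either group D library left out are Chdh, Dnaic2, Gata1, Aldh1a2, Cyp26b1, Crabp1, Elmo1, Slc2a8, Plk1, Piwil1, Ccna1, Hsd3b1, Cdh5, Izumo1, Gpi1, Ptgds, Tex101, Jam2 and Cry2. The last 6 of these also did not pass without other libraries: Jam2 and Cry2 were lost in 7 of the 10 fits with a library left out, Ptgds and Tex101 in 6, Gpi1 in 5 and Izumo1 in 3. Fam107a, Jag1, Aif1 and Actg2 did not pass without group D replicate 1, Clstn3 without group D replicate 2, and Catsper3 without group D replicate 2 or group E replicate 1.

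Of the 8 measured androgen-responsive Sertoli genes, 4 rose in D (6 adjusted over the list alone) and 4 did not pass, with Rhox5, a homeobox gene, up by 2.06 (SE 0.22) and the dopamine receptor Drd4 by 2.73 (SE 0.41). The list's camera test gave adjusted p = 3.72e-08, and adjusted p = 0.247 with an estimated correlation. Of 18 retinoid genes, 4 rose and 3 fell (5 and 3 adjusted over the list alone). Stra6 and Aldh1a2, which makes retinoic acid (1.68, SE 0.30), rose, while Cyp26b1, which degrades it (-1.42, SE 0.30), and the binding protein Crabp1 (-2.02, SE 0.47) fell; the list as a whole was not called. Among the 25 Sertoli core genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone), the latter Espn, an actin bundler of Sertoli junctions, from 1833 CPM ± 247 in B to 416 CPM ± 54.0 in D. Gata1 rose by 1.27 (SE 0.27). The junction list had 1 of 15 members higher, Jam2, and 1 lower, Espn (2 and 1 adjusted over the list alone). For lysosome and phagocytosis 3 of 20 fell, among them Gas6 and Elmo1 (also 3 adjusted over the list alone), and the median (0.08) and mean (-0.19) of that list differ in sign.

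Glycolysis and lactate export had 1 of 21 members higher, the lactate exporter Slc16a3 (2.65, SE 0.35), and 3 lower, among them Slc2a8 and Gpi1 (2 and 3 adjusted over the list alone). Cholesterol synthesis had 1 of 19 members higher, and Jag1 fell as 1 of 10 niche growth factors (1 higher and 3 lower, respectively, adjusted over the list alone). Cry2 rose as 1 of 14 clock genes and Plk1 fell as 1 of 20 cell cycle genes (1 higher and 4 lower, respectively, adjusted over the list alone). None of 12 proteases and inhibitors passed by edgeR over all genes (4 higher and 1 lower adjusted over the list alone), with Ctsl at a log2 change of 0.76 (SE 0.23, adjusted p = 0.0592) and Timp2 at 0.29 (SE 0.23). No gene of the 17 of the immediate early and dissociation stress list passed, over all genes or adjusted over the list alone, with Jun at 0.00 (SE 0.28) and Jund at -0.07 (SE 0.24). None of these lists was called by camera.

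Among 17 elongating spermatid genes, 10 fell in D (12 adjusted over the list alone), led by Prm1 and Tnp1 (-2.98, SE 0.25), with camera adjusted p = 4.21e-19, and adjusted p = 0.247 with an estimated correlation. Their share of all counts was 0.451% ± 0.097 in D and 1.72% ± 0.18 in B (SD, n = 2). Among 15 round spermatid genes, 2 rose, Catsper3 (1.93, SE 0.45) and Izumo1 (1.60, SE 0.38), and 7 did so adjusted over the list alone, with adjusted p = 0.0129, and adjusted p = 0.709 with an estimated correlation. Spermatocyte genes had 2 of 19 higher, Piwil1 and Tex101, and 1 lower, Ccna1 (3 and 1 adjusted over the list alone), and spermatogonial genes had 1 of 15 lower, Etv5 (-1.67, SE 0.24; also 1 adjusted over the list alone). For other testis cells, 3 of 7 Leydig genes rose, among them Hsd3b1 and Ptgds, and 2 of 6 endothelial genes, Tek and Cdh5 (3 each adjusted over the list alone). Actg2 fell as 1 of 9 myoid genes and Aif1 as 1 of 4 macrophage genes (1 higher and 1 lower, and 3 lower, respectively, adjusted over the list alone). Alas2 was the blood gene measured. None of 7 stroma genes passed, with Fbln1 at 0.09 (SE 0.25) and Col1a2 at 0.25 (SE 0.35), nor did any adjusted over the list alone.

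**Figure D3:**
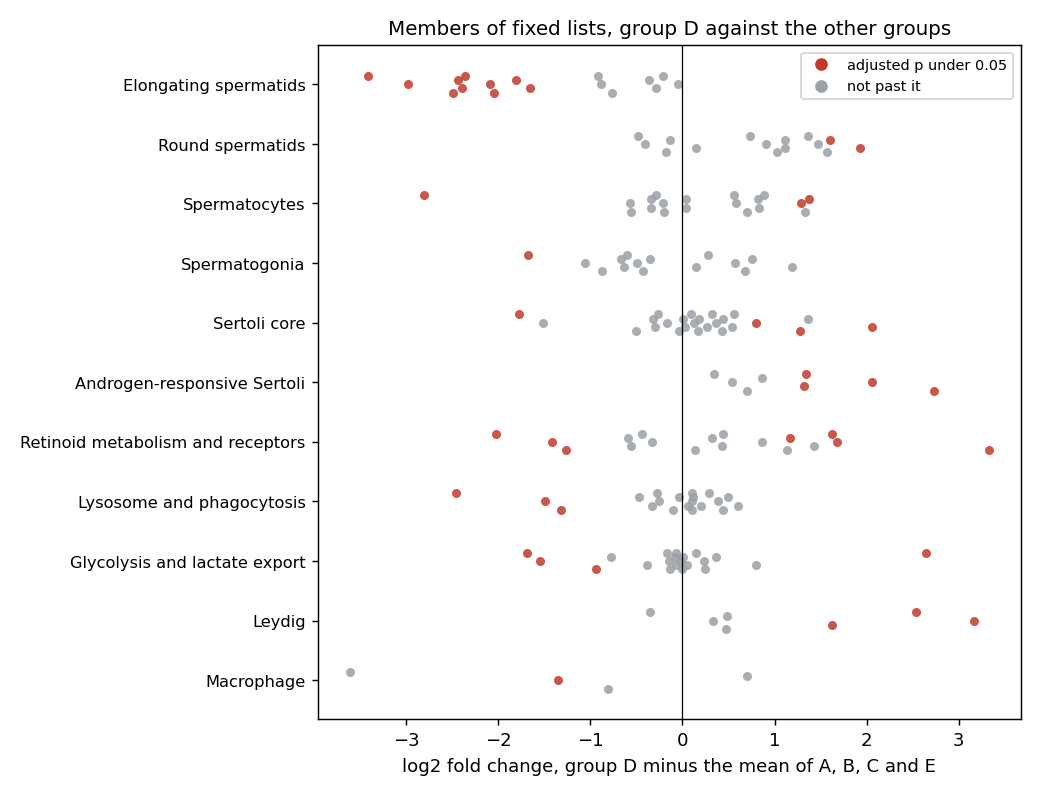
Log2 fold change of each measured member of 11 fixed lists, group D minus the mean of the other groups (each point 1 gene; red, adjusted p under 0.05; grey, not past it). Of the elongating spermatid genes 10 lie in red below 0, and of the round spermatid genes 2 lie in red above it.

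Of 611 genes lower in D and tested in both sets, 319 (52.2%) were under 0.1 times the sorted level in NANOS2 KO, against 104 of 616 higher in D (16.9%) and 13.3% of 12767 uncalled genes; these shares were not tested. With genes of at least 1 CPM in the NANOS2 KO alone, a setting added after the data were seen, 773 genes differed in D, 458 higher and 315 lower.

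The remaining groups were compared with the rest in the same way. Group A, stages XI-XII, had 113 genes higher and 127 lower. Mest (2.01, SE 0.31), Gda, Prss58 and Fam84b were high, and Padi2 (-4.27, SE 0.59), Drd4 (-4.14, SE 0.66), S100a1 and Ano1 low. Of these, Fam84b did not pass in 8 of the 10 fits with a library left out, Gda in 7, and Mest without group A replicate 1. In A, 4 of 8 androgen-responsive genes fell (also 4 adjusted over the list alone; camera adjusted p = 2.01e-08, and adjusted p = 0.538 with an estimated correlation), and 4 of 17 elongating spermatid genes rose (7 adjusted over the list alone; adjusted p = 2.01e-08, and adjusted p = 0.826 with an estimated correlation). Round spermatid genes were lower in A as a list (adjusted p = 0.000981, and adjusted p = 0.858 with an estimated correlation), with none of 15 past the gene test and 2 lower adjusted over the list alone. Group C, stages IV-VI, had 280 genes higher and 99 lower. Padi2 (3.10, SE 0.35), S100a1 (3.04, SE 0.23), Ptpn7 and Adam8 rose, while Prss52 (-3.56, SE 0.70), Prss51, Cmbl and Prss37 fell. Without either group C library these 4 falls did not pass, and that of Prss37 was lost in 6 of the 10 fits. Group C also had 2 of 8 androgen-responsive genes higher (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0185, and adjusted p = 0.948 with an estimated correlation), and 1 of 20 cell cycle genes (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.0499, and adjusted p = 0.948 with an estimated correlation).

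Group E, stages IX-X, had 36 genes higher, among them Prss52 (2.52, SE 0.43), Prss37, Actrt3 and Trp53tg5, and 39 lower, among them Mical2 (-2.74, SE 0.31), Ptk2b, Frmpd1 and the water channel Aqp8 (-2.44, SE 0.30). Peritubular myoid genes were lower in E as a list (adjusted p = 0.0189, and adjusted p = 0.701 with an estimated correlation), with none of 9 past the gene test, over all genes or adjusted over the list alone. Cell cycle genes were lower too (adjusted p = 0.00736, and adjusted p = 0.97 with an estimated correlation), with none of 20 past it and 2 lower adjusted over the list alone. Elongating spermatid genes were higher as a list (adjusted p = 0.0189, and adjusted p = 0.97 with an estimated correlation), with none of 17 past it and 3 higher adjusted over the list alone. Group B, stages I-III, had 6 genes higher and 0 lower by edgeR, with 1298 at an unadjusted p under 0.05 and 77 higher and 35 lower by DESeq2. The genes that the naming rule takes include Ptpn7 (2.68, SE 0.33), Alas2 (1.89, SE 0.28) and Prm1 (1.45, SE 0.21). In B, 1 of 17 elongating spermatid genes rose (10 adjusted over the list alone; adjusted p = 5.98e-13, and adjusted p = 0.428 with an estimated correlation). No gene passed in 4 other lists called in B at the preset correlation: cell cycle higher (adjusted p = 0.0277), macrophage higher (adjusted p = 0.0273), androgen-responsive lower (adjusted p = 0.0273; 1 lower adjusted over the list alone) and spermatocytes lower (adjusted p = 0.0428). With an estimated correlation the adjusted p was 0.428 for macrophage genes and 0.765 for the other 3. In B, Prm1 and Alas2 did not pass in 6 of the 10 fits with a library left out and Ptpn7 in 4. All 8 genes named for E were lost without either group E library, and Prss52, Prss37, Actrt3 and Trp53tg5 in 5 of the fits. Without one library at a time the counts ran from 85 to 297 in A, from 0 to 72 in B, from 163 to 580 in C and from 0 to 296 in E. On genes of at least 1 CPM in the knockout, fewer passed in A and E, as given below. That setting was added after the data were seen.

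Steps from one group to the next were largest after group D. From D to E, 285 genes rose and 225 fell: Tnp1 rose by 3.01 (SE 0.27) and Prm1 by 3.02 (SE 0.31), and Ndrg4 fell by 3.64 (SE 0.34) and Rhox5 by 2.21 (SE 0.32) on the log2 scale. From C to D, 88 genes fell, Ptpn7 by 5.55 (SE 0.61), Gas6 by 2.52 (SE 0.29) and Espn by 1.59 (SE 0.25), and 2 rose, Gsta3 and Tbc1d10c. From B to C, 6 genes rose, among them Actn3, Rhox5, Ndrg4 and S100a1, and 2 fell. From A to B the single call was a rise of Pcyt1b (2.73, adjusted p = 0.0493). From E to A edgeR called 0 genes, with 729 at an unadjusted p under 0.05 and 38 called by DESeq2. Gsta3, Tbc1d10c and the genes of the steps were chosen after their values were seen. Left-out libraries moved these counts from 37 (without group E replicate 1) to 826 for D to E, from 0 (without either group D library) to 378 for C to D, and from 0 to 85, 10 and 15 for B to C, A to B and E to A.

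The second set asks whether a testis without germ cells changes over the days of one cycle. With edgeR and its filter few genes differed by day, and their number depended on the processing, as given below. Myh6, a myosin heavy chain, stood at 94.1 CPM ± 4.64 on day 48 and 10.1 CPM ± 2.02 on day 42 (SD, n = 2 each). Snhg11 reached 97.1 CPM ± 11.9 on day 48, and the kallikrein Klk1b27 141 CPM ± 0.28 on day 48 against 4.79 CPM ± 2.52 on day 49. Tap2, a peptide transporter of antigen presentation, reached 50.3 CPM ± 0.34 on day 49, against 14.7 CPM ± 0.14 on day 42. H2-Q4, a class I histocompatibility gene, was at 124 CPM ± 59.9 on day 49 and 43.2 CPM ± 4.87 on day 48. In all, 76 of 13065 genes differed by day (adjusted p = 0.000118 for Myh6, edgeR). Day 49 replicate 2 and day 42 carry weight: 879 genes differed without that replicate, 109 without day 49, and 18 without day 42 library 1. H2-Q4 did not pass without day 49 replicate 2.

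**Figure D4:**
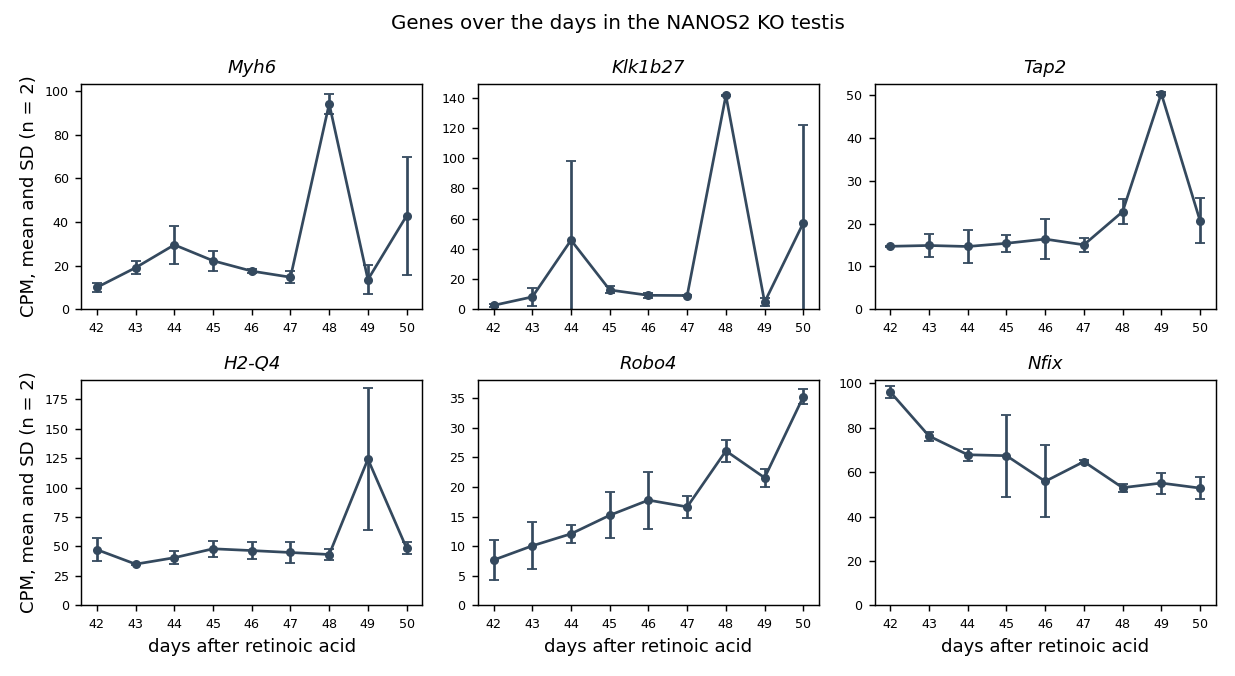
CPM of 6 genes in the NANOS2 KO testes by day after retinoic acid (points, mean of 2 libraries; error bars, SD). Myh6 and Klk1b27 have their highest mean on day 48, with 94.1 and 141 CPM, Tap2 on day 49 with 50.3 CPM, and Robo4 climbs to 35.2 CPM on day 50.

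A straight line over the days was past the threshold for 112 genes, 64 rising and 48 falling. Robo4, a receptor of endothelial cells, rose by 0.24 per day on the log2 scale (SE 0.03, adjusted p = 7.87e-06), from 7.66 CPM ± 3.33 on day 42 to 35.2 CPM ± 1.26 on day 50. Ier2, an immediate early gene, rose by 0.12 (SE 0.02), as did Gsr and Akap1 (0.08 each), while the transcription factor Nfix fell by 0.10 (SE 0.02) and Capn6 by 0.09 (SE 0.02) per day. Of 17 immediate early genes, 4 rose (7 adjusted over the list alone; adjusted p = 1.55e-05, and adjusted p = 0.0729 with an estimated correlation). Leydig genes moved up as a list, with 1 of 11 past the gene test (7 adjusted over the list alone; adjusted p = 1.55e-05, and adjusted p = 0.276 with an estimated correlation). Cholesterol synthesis genes did so with none of 19 past it, over all genes or adjusted over the list alone (adjusted p = 0.0116, and adjusted p = 0.613 with an estimated correlation). Stroma genes moved down, with 1 of 10 past the gene test (3 adjusted over the list alone; adjusted p = 0.000797, and adjusted p = 0.134 with an estimated correlation). None of 25 Sertoli core genes passed for a trend. Nfix did not pass without either day 42 library, Capn6 without these or day 43 replicate 1, Gsr without these or day 50 replicate 1, and Akap1 without day 42 library 1, day 43 replicate 1 or day 50 replicate 1. The count was 4 without day 42 library 1, 5 without day 43 replicate 1, 13 without day 50 replicate 1 and 300 without day 49.

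A smooth cycle of 8.6 days, the length of the mouse seminiferous cycle, fitted no gene at the threshold: edgeR called 0, with 1262 at an unadjusted p under 0.05, a smallest adjusted p of 0.0606, and 57 called by DESeq2. Without day 49 the count was 7. Of 749 genes that differed among the stage groups and were tested in both sets, 18 (2.40%) also differed by day, against 0.353% of the other genes tested in both (odds ratio 6.96, 95% interval 3.72 to 12.6, Fisher's exact test over genes, two-sided p = 7.11e-09, adjusted 1.38e-08). For the straight line the shared genes were 22 (odds ratio 4.63). Group D genes gave 18 by day (odds ratio 6.44) and 26 by the line (odds ratio 5.39). Genes are not independent replicates, so these p-values describe the lists. The other genes were not matched on expression, which bears on what both tests can call. The overlap alone therefore does not show a stage programme in the knockout. At an unadjusted p under 0.05 for the cycle, 172 of the 749 passed, against 8.95% of the others.

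The third comparison sets the testis without germ cells against sorted Sertoli cells from testes with them. Genotype, strain, whole testis against sorted cells and deposited table all change together here. Sorted libraries also hold transcripts of the germ cell lists, with 1.28% of the counts on the 17 genes of the elongating spermatid list alone. The share of all germ cell RNA in them was not measured and can be larger. A lower level in the knockout therefore need not be a change in Sertoli cells. Nor need a higher level, since whole testis holds other cells. The Leydig list took 0.528% of the counts in the knockout and 0.0332% in sorted libraries, and the stroma list 0.182% and 0.0142%. Transcripts of late germ cells were near absent from NANOS2 KO: Prm2 had 2 counts over the knockout libraries and 3108 CPM ± 1619 (SD, n = 10) in sorted cells, and Ldhc, a lactate dehydrogenase of germ cells, 1 count and 1387 CPM ± 483. Spata20, Akap4 and Smcp had 0 counts in the knockout and were at least 17244-fold, 17031-fold and 14196-fold lower there than in sorted cells, with a floor of 3 counts over the group. Tnp1, Tnp2, Tcp11, Gsg1 and Oaz3 had 2 to 4 counts in the knockout. Steroidogenic genes ran the other way. Cyp11a1, the first enzyme of steroid synthesis, was at 1040 CPM ± 426 (SD, n = 18) in the knockout and 1.91 CPM ± 2.61 in sorted cells. Hsd3b6 was at 910 CPM ± 178 against 0.27 CPM ± 0.37. Lhcgr, the luteinizing hormone receptor, and Ces1d had 0 counts in sorted cells and were at least 1674-fold and 2368-fold higher in the knockout. Bhmt, Apoc1, Pon3, Figf, Cbr2 and the macrophage lysozyme Lyz2 (211 CPM ± 40.6 against 0.41 CPM ± 0.49) complete the 10 largest rises.

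Of 15777 genes, 6003 were higher and 7416 lower in the knockout (edgeR), with a median log2 fold change over all genes of -0.17. Counted with limma on log2(CPM + 1), which carries no TMM scaling, the split was 7976 higher and 5835 lower. Tested against a 2-fold change, a setting added after the data were seen, 3215 were higher and 4020 lower.

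Of the germ cell lists, 19 of 19 spermatocyte genes were lower in the knockout (adjusted p = 3.42e-14), 15 of 15 round spermatid genes (adjusted p = 1.29e-05, and adjusted p = 0.207 with an estimated correlation) and 17 of 17 elongating spermatid genes (adjusted p = 1.11e-34). For spermatogonia 12 of 15 fell, Ddx4 and Uchl1 among them, and 2 rose, Kit (2.63, SE 0.14) and Zbtb16 (1.05, SE 0.19), with adjusted p = 0.00662, and adjusted p = 0.165 with an estimated correlation. All 11 Leydig genes rose, as did all 9 endothelial genes, Eng and Cdh5 among them. Stroma genes had 9 of 10 higher, with Dcn at 402 CPM ± 77.2 against 1.22 CPM ± 0.67, and macrophage genes 11 of 13, with Csf1r at 134 CPM ± 18.1 against 1.39 CPM ± 0.82. Myoid genes had 8 of 10 higher, Myh11 among them (3.95, SE 0.15; adjusted p = 0.00119, and adjusted p = 0.0525 with an estimated correlation). Members of those lists that were lower in the knockout stood high in sorted cells: Aif1 at 194 CPM ± 81.8, Actg2 at 190 CPM ± 98.7, Fbln1 at 116 CPM ± 37.7 and, among 5 blood genes of which 4 rose, Alas2 at 486 CPM ± 364. The blood list was not called by camera. Adjusting over each list alone gave the same numbers of calls for every list of this comparison. The calls of the spermatocyte, elongating spermatid, Leydig, endothelial, stroma and macrophage lists held with an estimated correlation.

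Sertoli core genes went both ways, 9 of 25 higher and 11 lower, with no call for the list. Their share of all counts was 1.29% ± 0.16 in sorted libraries (SD, n = 10) and 1.91% ± 0.07 in the knockout (n = 18). Kitl, a growth factor for spermatogonia, was at 164 CPM ± 27.2 in the knockout (n = 18) and 40.1 CPM ± 14.3 in sorted cells (n = 10), and Amh at 65.4 CPM ± 20.6 and 11.7 CPM ± 8.07. Aard fell by 1.35 (SE 0.06) and Dmrt1 by 1.32 (SE 0.07) on the log2 scale. Androgen-responsive genes had 3 of 8 higher, Serpina5 (1.27, SE 0.10) among them, and 4 lower, Rhox5 (-1.76, SE 0.11) and Tubb3 (-1.27, SE 0.11) among them; the median of that list was -0.36 and its mean 0.05. Retinoid genes had 7 of 19 higher, among them Aldh1a1 (1951 CPM ± 257 against 537 CPM ± 169) and Adh1, and 7 lower, among them Aldh1a2 (-2.04, SE 0.16) and Rdh11. Neither list was called.

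Niche growth factors had 15 of 20 members higher and 5 lower, led by Cxcl12 (155 CPM ± 27.7 against 1.10 CPM ± 0.83) and Csf1 (101 CPM ± 10.5 against 0.81 CPM ± 0.63), with Jag1 and Jag2 lower (adjusted p = 2.69e-05, held with an estimated correlation). Cholesterol synthesis genes had 16 of 19 higher, Cyp51 (2.26, SE 0.10) among them, and Fdft1 lower (adjusted p = 1.55e-05, and adjusted p = 0.0525 with an estimated correlation). Proteases and inhibitors had 13 of 17 higher, Ctsh and Adamts1 among them, and Cst9 and Plat lower (adjusted p = 0.00357, and adjusted p = 0.207 with an estimated correlation). Glycolysis genes had 17 of 21 lower, among them Hk1 (55.1 CPM ± 6.53 against 1229 CPM ± 417) and Ldha (-2.70, SE 0.09), and 4 higher, among them Aldoc and Slc16a3 (adjusted p = 0.0105, and adjusted p = 0.189 with an estimated correlation). Cell cycle genes had 18 of 20 lower, Top2a and Aurka among them, and Mcm4 higher (adjusted p = 0.000275, and adjusted p = 0.205 with an estimated correlation). Junction genes had 8 of 16 higher, Cldn5 and Jam2 among them, and 4 lower, Espn and Cldn3 among them. Lysosome genes had 8 of 20 higher, Mertk among them, and 8 lower, Atg7 and Map1lc3b among them. Clock genes had 9 of 16 higher, Per3 and Hlf among them, and 5 lower, Cry1 and Rora among them. Immediate early genes had 13 of 18 lower, with Fosb at 1.26 CPM ± 0.75 against 66.6 CPM ± 15.6 and Fos lower too, and 3 higher, Myc and Klf6 among them. These last 4 lists were not called. Which cells of the whole testis carry the genes that were higher was not measured.

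**Figure D5:**
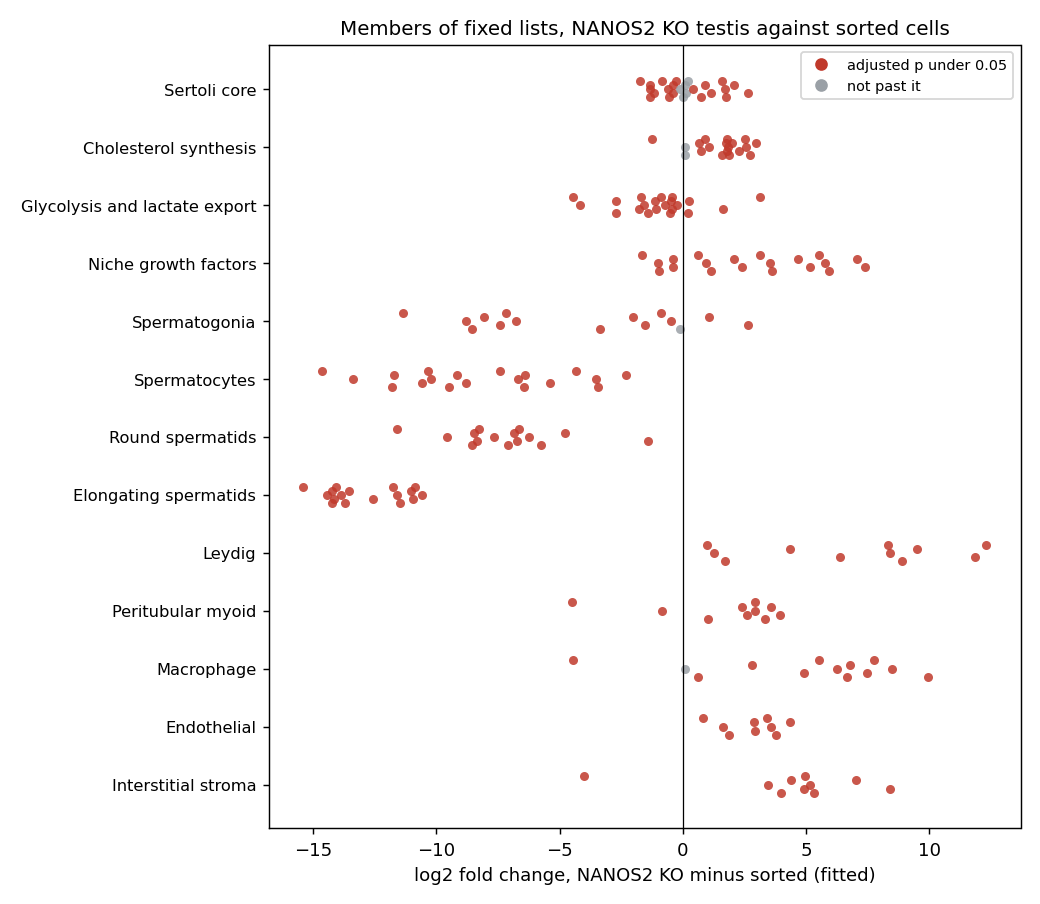
Log2 fold change of each measured member of 13 fixed lists, NANOS2 KO testes minus sorted cells as fitted (each point 1 gene; red, adjusted p under 0.05; grey, not past it). Fitted changes of genes near 0 counts in 1 set depend on the prior count. All 17 elongating spermatid genes lie below 0 and all 11 Leydig genes above it.

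The last question is which sorted state the knockout testis is nearer to. Gene by gene, the knockout level was nearer D for 34.1% of 616 genes higher in D and 79.5% of 611 lower in D. For 12767 uncalled genes the share was 51.5%, and none of these shares was tested. A gene near absent from the knockout is nearer whichever sorted level is lower. Of the genes lower in D, 52.2% were under 0.1 times the sorted level in the knockout. Both sets were also picked for their levels in D, so these shares do not show which state the knockout is nearer to. The knockout level of genes high in D varied: the log2 fold change, knockout minus D, was -5.64 (SE 0.37) for Stra6, -3.41 (SE 0.16) for Rhox5, -3.18 (SE 0.23) for Actn3 and 2.52 (SE 0.28) for Prss35. Against group D, 4694 genes were higher and 6721 lower in the knockout (6416 and 5191 with limma on log2(CPM + 1)), and against the other 4 groups 5982 and 7299 (7978 and 5694 with limma). The first contrast rests on 2 sorted libraries and the second on 8, so the counts do not rank the groups. Most calls were shared: 4389 genes were higher and 6127 lower in the knockout in both contrasts, while 78 lay above D and below the others and 112 below D and above the others. The distance to the knockout mean over all genes was 2.17 ± 0.11 for D (SD, n = 2) and 2.31 ± 0.09 for the other groups (n = 8; exact permutation test, two-sided p = 0.111, chosen after the counts were seen). Over 13492 genes of at least 1 CPM and at least 0.1 times the sorted level in the knockout it was 1.56 ± 0.05 for D and 1.61 ± 0.06 for the others (exact permutation test, p = 0.333). Over the Sertoli core list it was 1.38 ± 0.12 for D and 1.24 ± 0.18 for the others (exact permutation test, p = 0.333).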

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

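Restricting the stage tests to genes of at least 1 CPM in the knockout, leaving out day 49 and testing against a 2-fold change were chosen after the data were seen. With RLE scaling all 13 counts recomputed stayed within 1.5 times their value. No named gene changed direction under the settings run for named genes. With limma on log2(CPM + 1) more genes were higher than lower in the knockout in all 3 comparisons with sorted cells. Against all of them limma gave 7976 higher and 5835 lower, the other way round from edgeR with 6003 and 7416. The CPM carry no TMM factor, whereas edgeR used joint factors with a median of 0.836 in sorted libraries and 1.10 in the knockout. These factors lower the knockout against sorted cells, so the scaling moves the split in this direction. Other differences between the methods were not tested apart.

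For the 5 groups, where edgeR called 1156 genes, no filter gave 2764, DESeq2 2000, limma without a filter 500, the germ cell covariate 2288, and genes of at least 1 CPM in the knockout 705. Group D, with 1239, gave 1932 without a filter, 1985 with the covariate and 773 on those genes. The covariate is 1 mean over spermatocyte, round and elongating spermatid genes, whose median log2 changes in D were 0.04, 1.03 and -1.80. These offset each other in the mean, so the counts with the covariate do not show that germ cell RNA was accounted for. Group A, with 240, gave 901 without a filter, 527 with DESeq2, 477 with the replicate block and 143 on those genes. Group B, with 6, gave 307, 112 and 24 with no filter, DESeq2 and the block, and 0 with limma on log2(CPM + 1). Group C, with 379, gave 988 without a filter and 649 with DESeq2. Group E, with 75, gave 651, 294 and 170 with no filter, DESeq2 and the block, and 20 on genes of at least 1 CPM in the knockout.

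DESeq2 and the block gave 35 and 8 genes for A to B, 204 and 39 for B to C, 309 and 178 for C to D, and 839 and 874 for D to E. For E to A, DESeq2 gave 38. Nothing in the labels says what a replicate number shares. Replicate differences correlated at over 0.1 in 6 of 10 pairs of sorted groups (median 0.197, from -0.11 to 0.43) and in 1 of 36 pairs of days (median -0.0049), so a shared factor in some sorted groups stays possible.

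For the 9 days, where edgeR called 76, no filter gave 968, DESeq2 215, and limma 43, 23 and 0 with 1 added, 0.1 added and no filter. The cyclic fit, with 0, gave 359 without a filter, 57 with DESeq2 and 7 without day 49. The straight line, with 112, gave 212 with DESeq2, 65 with the block, 26, 21 and 4 with the 3 limma settings, and 300 without day 49. Against a 2-fold change, 7235 genes differed between the knockout and all sorted libraries, 6283 against D and 7216 against A, B, C and E. Of 146 list tests 34 were called at the preset correlation, and 7 with an estimated correlation. The counts on genes of at least 1 CPM in the knockout come from the same p-values adjusted over those genes alone. Besides genes left out, calls were lost among genes still tested: 512 genes higher and 356 lower in D were at that level, and 458 and 315 passed. For the other settings the cause was not tested.

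Leaving out each library gave 386 to 1518 genes for the 5 groups, 289 to 1739 for D, 85 to 297 for A, 0 to 72 for B, 163 to 580 for C and 0 to 296 for E. The steps gave 0 to 10 (A to B), 0 to 85 (B to C), 0 to 378 (C to D), 37 to 826 (D to E) and 0 to 15 (E to A). The days gave 18 to 879, the cycle 0 to 9 and the line 4 to 215. The knockout gave 13226 to 13431 against all sorted libraries, 9149 to 11619 against D and 12995 to 13297 against the others. Relative distances ran from 0.94 to 1.02 for A, 0.88 to 0.95 for B, 0.99 to 1.11 for C, 1.07 to 1.19 for D and 0.88 to 0.97 for E. Of 192 values of named genes, 136 were past the threshold in every fit with a library left out. DESeq2 kept 191 on the same side, limma 179, and the block and RLE all 192. The 192 include list members that were not past the threshold in the full fit, Ctsl and Jun among them.

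With 2 libraries per group at these depths, simulated changes of 1 on the log2 scale were recovered for 8.96% of genes by the F test over the 5 groups, and changes of 3 for 98.4%. Neither depth nor group size was varied, so their shares in this limit are not known. All genes were simulated with 1 coefficient of variation, so recovery of real changes can differ.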

Other observations

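All tests of this part were chosen after the results they concern were seen. Leydig genes varied between knockout libraries: the mean deviation of the 11 list members from their mean over the days was -0.67 and -0.57 (log2) in the libraries of day 42, 0.66 and 0.58 on day 48, -0.42 and -0.16 on day 49, and 0.74 and 0.11 on day 50.

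The first pattern concerns genes of group D in the testis without germ cells. Over the 18 libraries, the mean z score of 459 genes higher in D and that of 311 genes lower in D ran against each other (Pearson r = -0.66, permutation p = 0.00443; Spearman rho = -0.78, permutation p = 0.00028; r = -0.51, permutation p = 0.0448, without the 2 farthest libraries). Their difference followed a cycle of 8.6 days with 57.2% of its variance (permutation p = 0.00101), from -0.56 ± 0.18 on day 43 to 0.62 ± 0.38 on day 49 (SD, n = 2). It also followed a straight line over the days (Pearson r = 0.605, permutation p = 0.0075), and the 9 days cover about 1 period. All these permutations moved single libraries, although the 2 libraries of a day share that day. A shift common to a day can therefore lower their p-values, and no whole day was left out. Its variance was 6.80 times the highest of 1000 random pairs of gene sets. The correlation of those pairs had a median of 0.20 and a lowest value of -0.68, beyond the observed one. The random genes were matched on expression but not on how they vary together, and were drawn from genes not called for D. Genes picked for varying together keep more variance in their mean, so the ratio does not single out a group D programme. The highest score, 0.88, is that of day 49 replicate 1 (0.35 in replicate 2), which also has the lowest mitochondrial share, 0.715% against 2.33 to 3.24% in the other knockout libraries. Against 1 library as the cause stands that the largest permutation p of the cycle with a library left out was 0.0027. Drift with age cannot be told apart from a cycle, since the cyclic terms beside a straight line gave a permutation p of 0.0593. A changing share of Sertoli cells in the whole testis stays open too: 21 Sertoli core genes outside the score did not follow or oppose it at the threshold (r = 0.107, permutation p = 0.66). A stage-linked programme that Sertoli cells may keep without germ cells, and a change in another cell type, are open and untested.

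The second pattern is the low level of late spermatid RNA in group D. Against less germ cell RNA of every kind as the whole cause stands that the median log2 change of 34 spermatocyte and round spermatid genes was 0.64 (SD 0.94), against -1.80 (SD 1.05) for 17 elongating spermatid genes. By list, the median was 1.03 for round spermatids, 0.04 for spermatocytes and -0.43 for spermatogonia, so a smaller fall of some germ cell RNA stays open. A candidate explanation is RNA of germ cells in the sorted fraction that changes with stage. Of 611 genes lower in D, 52.2% were under 0.1 times the sorted level in the testis without germ cells, against 13.3% of 12767 uncalled genes. Sertoli genes that are low without germ cells would give such a share too, so it does not decide for this explanation. How much of the difference between D and the other groups comes from Sertoli cells themselves was not measured.

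The third pattern is the high level of antigen presentation genes on day 49 of the knockout. In replicate 2 of that day the median log2 deviation of 30 interferon genes outside chromosome 17 was 1.60, and at most 0.325 on other days. This argues against a strain variant in the histocompatibility region as the whole cause in replicate 2, and an interferon response is a candidate explanation there. In replicate 1 the same genes stood at 0.112, within the range of the other days, as a strain variant would leave them, so such a variant stays open for that library. A response in replicate 2 alone leaves unexplained that Tap2 stood at 50.3 CPM ± 0.34 over both libraries (SD, n = 2). Genes of the histocompatibility region had medians of 0.95 in replicate 1 and 1.73 in replicate 2, but were picked from the calls by day, so these values decide nothing about the cause.

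The number of genes that differ between the knockout and sorted cells was set beside that of other splits of the same libraries. Of 40 splits fitted with 2 groups, only the real one gave as many as 13295 genes. The highest of the other splits gave 7103, and such a number points to a structure of the samples. Against groups A, B, C and E only the real split of 40 gave as many as 13249, and the highest other gave 3473. Genotype, strain, whole testis against sorted cells and deposited table change together between the sets. The real split would therefore give the most genes whatever the cause, so these splits decide nothing about chance or about any of these differences.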
